A study of Mus musculus with 8 samples.

How the data were processed

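MicroRNA (miRNA) levels were measured in primary mouse oligodendrocytes, the cells that form myelin in the brain, at 3 ages in culture. The labels give strain C57BL/6J and the genotype CNP-Cre, in which the Cre recombinase stands under the promoter of a gene of the oligodendrocyte lineage. Per the labels' protocols, the cells were shaken off and plated in a defined medium with B27, a low share of horse serum and thyroid hormones, and total RNA was taken with Trizol, labelled with Cy3 and hybridised to Agilent arrays, 1 sample per array. The labels name 3 arrays of day 0 and 2 of day 1, both called immature, and 3 of day 6, called mature. The series text calls the samples independent; it counts the immature cultures from another starting day than the sample labels do, and the day numbers of the labels are used here. Whether samples came from different animals or litters is not given in the sources used here, so p-values measure only the spread between these samples.

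The deposited spot files come from Agilent Feature Extraction, version 9.5 per the file headers, a name the submitters' processing notes also give. Per the file headers, the values used are background-subtracted intensities on a linear scale, which can fall below 0, and they had not been scaled between arrays. The table of submitters' values holds the same deposited intensities, matched by spot number, with a largest difference of 0 from the spot files. Its scale is therefore known, it is not centred, and a higher value means more signal. Median intensities of the non-control spots in its columns were -6.93, 2.90 and 3.28 for day 0, 3.13 and 0.768 for day 1, and 2.83, 1.74 and 1.78 for day 6. All 8 arrays lay on 1 slide and carried 1 scan date, so slide and scan could not act as batches between days.

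Each array held 13715 spots, of which 13000 were not controls. They formed 1857 probes for 650 miRNAs, 611 of mouse and 39 of viruses. Spots flagged as outliers were left out and the spots of a probe averaged. A probe counted as detected on an array when at least a share of 0.5 of its spots was well above background. Each array was divided by its 75th percentile over the 91 probes detected on all arrays and brought to a common level. Signals under the 5th percentile of the detected values, 18.4 or 4.20 on the log2 scale, were raised to that floor before taking log2. The value of a miRNA is that of its brightest probe. Mouse miRNAs detected on at least 3 arrays were tested, which left 199; the remaining 412 were not. Folds against values at the floor depend on that floor and can understate or overstate a change, and values at the floor have no order. Star strands were left out of the lists. Precision is limited by the number of arrays.

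R 4.3 with limma 3.58 was used, with version 1.17 of the data.table package, and figures were drawn with Python 3.11 and matplotlib 3.10. A limma model with 1 mean per day was fitted to the log2 values of all 8 arrays, with empirical Bayes moderation and two-sided tests. Contrasts were day 6 against the mean of day 0 and day 1, and each pair of days. P-values were adjusted by Benjamini-Hochberg over the 199 miRNAs, and an adjusted p under 0.05 was a call. Of 20 lists fixed beforehand, the 14 with at least 3 tested members were compared with the other miRNAs by limma's camera with a preset correlation of 0.01. Camera with an estimated correlation and limma's fry were run beside it. The lists were the miR-17 to miR-92a family; oligodendrocyte differentiation and precursor miRNAs; let-7; the miR-15, miR-34, miR-30 and miR-181 families; the miR-23 and miR-183 clusters; the imprinted Dlk1-Dio3 clusters; the stem cell cluster; and markers of neurons, astrocytes, microglia, erythroid cells, fibroblasts, endothelium, epithelium and muscle.

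For the comparison of mature with immature cells, the rule for named miRNAs took the 12 largest rises and 12 largest falls among calls detected on all 8 arrays with separate groups. It added up to 4 calls in each direction that were undetected on 1 side, given as a bound. It also took every tested member of the miR-17 to miR-92a and oligodendrocyte differentiation lists, and the 2 members with the smallest adjusted p of every other list. For pairs of days it took up to 5 in each direction, or the 3 smallest p where fewer than 3 were called. Other called miRNAs are named because the counts are small, and were chosen after their values were seen. Tests, lists, the rule and most other settings were chosen before the data were examined. These settings concerned scaling, background correction, probe summary, floor, detection filter, outlier spots, the moderation of the variance, a replicate block, the arrays in the fit, the grouping of the days, leaving out each array, and the list test. Array weights, the slide row as a block, scaling to control probes, an exact permutation of list means and the lists in day 6 against day 0 and against day 1 were added after the data were seen. The planned slide block could not be run with 1 slide.

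The procedure was tested on 100 simulated data sets with the means and spreads of the comparison of mature with immature cells, with 40 of 199 miRNAs changed. It recovered 49.0% of those changed by 1 on the log2 scale and 88.4% of those changed by 2, and 4.45% of its calls were wrong. Without any change, 6 of the 100 sets gave a call. For these shares the noise was independent between miRNAs, with the same spread on all arrays and no floor. The real arrays differ in this, so the shares need not hold for them. For the list of 10 family members without any shift, camera with the preset correlation passed p under 0.05 in 2% of the sets when members varied independently, and in 49% when they were correlated at 0.884 as estimated from these arrays. With the estimated correlation the latter share was 2%.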

Results

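The arrays followed miRNA levels while oligodendrocytes aged in culture, in order to find miRNAs of this lineage, and the title of the series names the miR-17 to miR-92a family. Immature cells were sampled on day 0 (n = 3) and day 1 (n = 2) and mature cells on day 6 (n = 3). Mouse miRNAs detected per array numbered 61, 187 and 218 on day 0, 202 and 150 on day 1, and 173, 179 and 170 on day 6. Day 0 replicate 1 stood apart, with a spread (scaled median absolute deviation) of its negative control spots of 30.2 against 2.54 to 3.88 on the other arrays. The SD of these spots, which outlying spots raise, was 50.3 there, but also 46.7 and 57.0 on day 6 replicates 1 and 3. It was 2.74 to 8.08 on the remaining arrays. Day 0 replicate 1 correlated with the other arrays across the 199 tested miRNAs at r between 0.832 and 0.881, against 0.884 to 0.968 among the others. The miRNAs are not independent replicates. No spot was saturated.

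In mature against immature cells, 4 of 199 miRNAs were called, all higher on day 6: miR-714, miR-711, miR-710 and miR-139-3p. None of the 4 was detected on all 8 arrays, so the rule for the largest changes named none. MiR-710 was well above background on all 3 day 6 arrays and on none of the 5 immature ones. It was at least 2.0-fold higher on day 6, a bound set by the lowest detected signal of each immature array. Its adjusted p of 0.0342 does not test this bound. It belongs to a log2 fold of 1.67 against immature values that all lay at the floor and so had no spread. The others were chosen after their values were seen. MiR-711 had a mean log2 signal of 6.91 ± 0.55 (SD, n = 3) on day 6 and was detected on 1 of the 5 immature arrays (log2 fold 2.34 ± 0.38 SE, adjusted p = 0.0242). MiR-139-3p stood at 6.35 ± 0.34 (SD, n = 3) on day 6 against 4.50 ± 0.29 (n = 3) on day 0 and 4.80 ± 0.82 (n = 2) on day 1 (log2 fold 1.71 ± 0.32 SE, adjusted p = 0.0342). MiR-714 (log2 fold 2.06 ± 0.33 SE, adjusted p = 0.0242) had 8.64 ± 0.19 on day 6 and 8.88 ± 1.02 on day 1 but 4.28 ± 0.13 on day 0, so that its difference lay between day 0 and both later days.

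**Figure D1:**
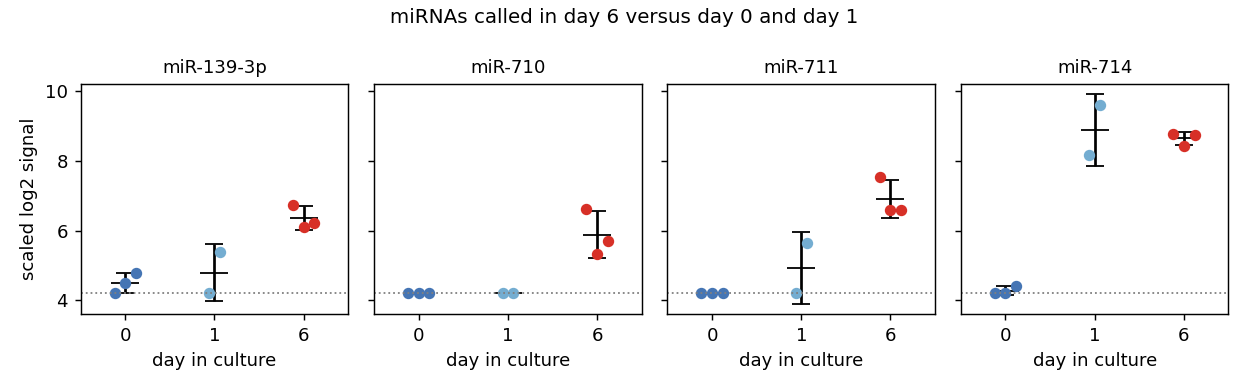
Scaled log2 signal of the 4 miRNAs called in mature against immature cells, by day in culture. Points are arrays, bars are the mean and SD of a day, and the dotted line is the floor of 4.20. MiR-714 is already high on day 1, with a mean of 8.88, and miR-710 leaves the floor only on day 6.

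A second probe for miR-710 had a log2 fold of 1.51, and its remaining probes were detected on 0 arrays. The other probes for miR-714 had log2 folds of 1.80 (detected on 6 arrays), 0.72 (5 arrays) and -0.19 (1 array). The remaining probes of miR-711 and miR-139-3p were detected on at most 1 array. The limma count fell to 0 without day 6 replicate 1 or without day 6 replicate 2, to 1 without day 6 replicate 3, and to 2 without day 0 replicate 2 or day 1 replicate 1; it was 8, with 7 higher and 1 lower, without day 0 replicate 1. It was also 0 with scaling over all probes, normexp, the mean of all probes, the summed signal per miRNA, no detection filter or only miRNAs detected on all arrays, 2 without scaling, and, in settings added after the data were seen, 0 with the slide row as a block, 10 with scaling to control probes and 11 with array weights. At an unadjusted p under 0.05 there were 24 miRNAs, 13 higher and 11 lower, with 9.95 expected by chance.

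The miR-17 to miR-92a family comprises 3 related clusters of miRNAs linked to cell proliferation. All 10 tested members had lower means on day 6 relative to the bulk of miRNAs, with a median log2 fold of -0.46. With scaling to control probes only 3 of the 10 had folds below 0, but all 10 stayed below the median of all miRNAs. The highest there was miR-19a at 0.24, against 0.55 for that median. Of the 10, 0 were called by limma, over all miRNAs or adjusted over the list alone. Camera called the list as lower than the other miRNAs with the preset correlation (adjusted p = 0.000374), but adjusted p = 0.920 with an estimated correlation. Fry, which asks whether members move together and compares them with no other miRNAs, gave an adjusted p of 0.691. An exact two-sided permutation of the family mean, chosen after the data were seen, gave p = 0.161 (day 6 7.80 ± 0.25, n = 3; immature 8.28 ± 0.43, n = 5). MiR-92a had the smallest p of the family, at 8.45 ± 0.20 on day 6 (SD, n = 3) against 9.01 ± 0.23 (n = 3) on day 0 and 9.47 ± 0.08 (n = 2) on day 1 (log2 fold -0.79 ± 0.21 SE, adjusted p = 0.126). MiR-20b and miR-20a had log2 folds of -0.68 and -0.67, miR-19b -0.52, miR-25 -0.47, miR-18a -0.46, miR-93 -0.44, miR-17 -0.40, miR-106b -0.32 and miR-19a -0.31. Members of near-identical sequence, such as miR-20a and miR-20b, can share signal on an array. The list call was also lost with scaling over all probes, and scaling to control probes turned the median to 0.088 while the median of all miRNAs moved to 0.55, so the direction holds only relative to other miRNAs.

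**Figure D2:**
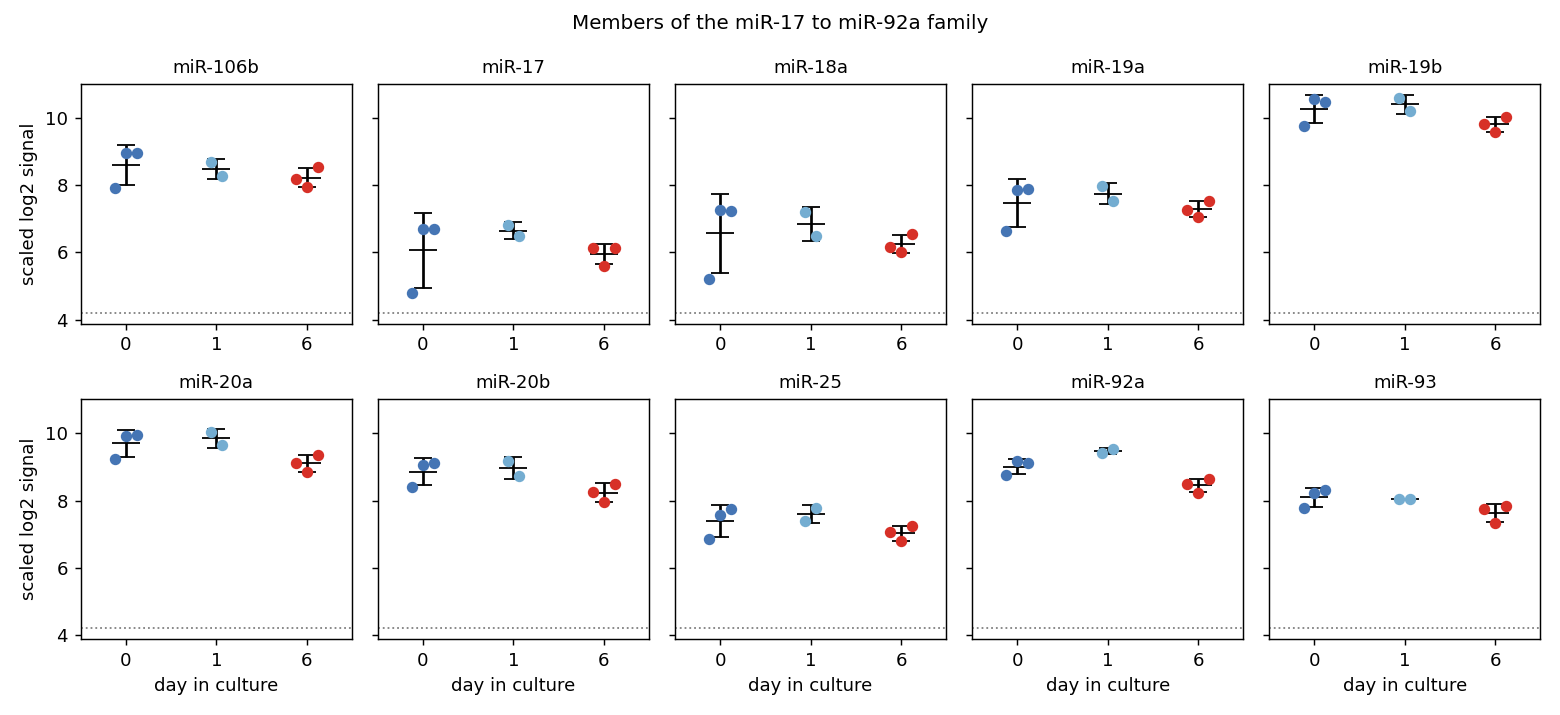
Scaled log2 signal of the 10 tested members of the miR-17 to miR-92a family by day in culture. Points are arrays, bars are the mean and SD of a day, and the dotted line is the floor of 4.20. Only in miR-92a do all day 6 arrays lie below all immature arrays; with scaling to control probes the family median turns to 0.088.

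The miRNAs known to promote oligodendrocyte differentiation varied widely within a day. All 7 tested members of that list had folds above 0, none called over all miRNAs or adjusted over the list alone (median log2 fold 0.19, camera adjusted p = 0.567). MiR-338-3p had 10.56 ± 0.90 on day 6 (SD, n = 3), 9.07 ± 2.28 (n = 3) on day 0 and 9.41 ± 2.48 (n = 2) on day 1 (log2 fold 1.32 ± 1.11 SE, adjusted p = 0.723). MiR-138 and miR-219, with the same known role, had log2 folds of 0.91 ± 0.83 SE and 0.80 ± 0.93 SE. MiR-23a and miR-23b, which act on lamin B1, had 0.07 and 0.14, miR-32 had 0.19 and miR-338-5p 0.09. The spread between arrays of 1 day exceeded these differences.

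**Figure D3:**
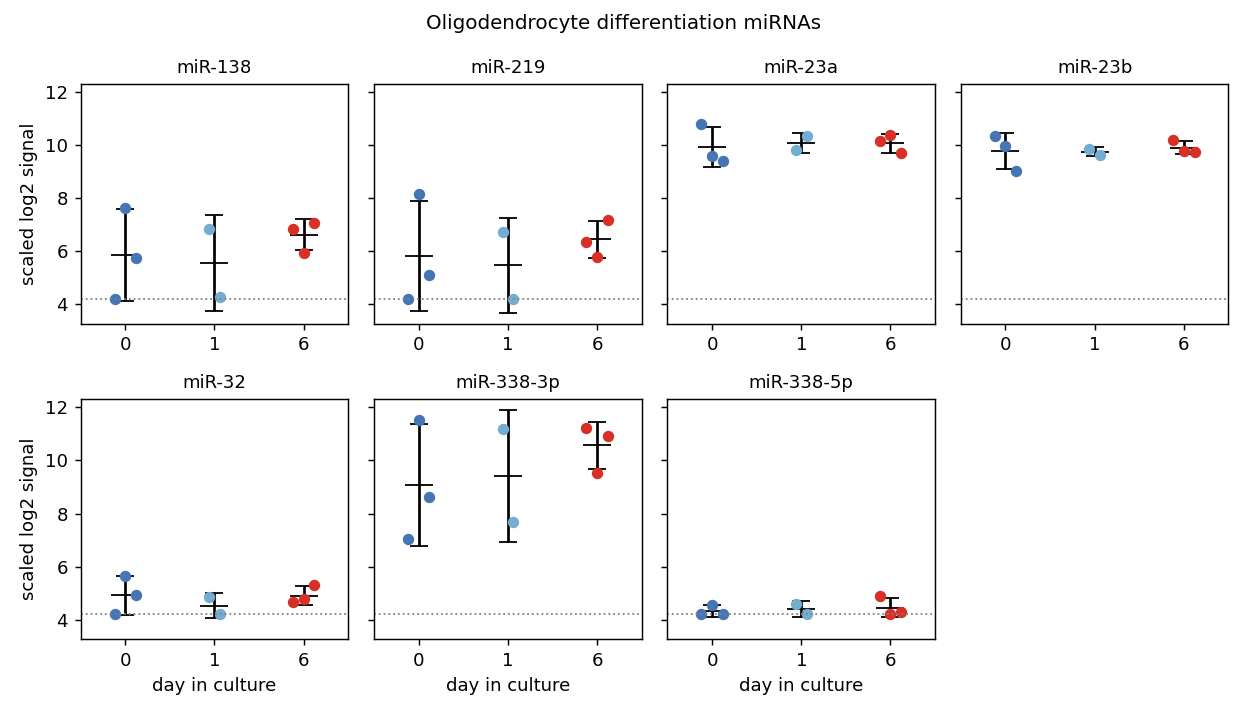
Scaled log2 signal of the 7 tested oligodendrocyte differentiation miRNAs by day in culture. Points are arrays, bars are the mean and SD of a day, and the dotted line is the floor of 4.20. MiR-338-3p spans 7.04 to 11.53 on day 0 alone, a range that holds all day 6 arrays.

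No other list passed the camera test in this comparison. Among 7 tested oligodendrocyte precursor miRNAs the median log2 fold was 0.47 (adjusted p = 0.834), with miR-335-5p at 1.01 and miR-7a at -0.63. The let-7 list (9 tested) had a median of 0.03 (adjusted p = 0.834), with let-7e at 0.41 and let-7i at 0.26. The miR-15 family (6 tested) had -0.12 (adjusted p = 0.380), and its miR-322, at -1.05 ± 0.26 SE, was not called over all miRNAs (adjusted p = 0.122) but was the 1 member below the threshold adjusted over the list alone; miR-15b had -0.27. Without day 0 replicate 1, miR-322 was called (adjusted p = 0.0346). The miR-34 family (4 tested) had a median of 0.43 (adjusted p = 0.834), with miR-449a at -1.26 and miR-34c at 0.59. The miR-30 family (5 tested) had -0.07 (adjusted p = 0.834; miR-30b -0.19, miR-30d -0.13), and the miR-181 family (4 tested) -0.23 (adjusted p = 0.530; miR-181d -0.70, miR-181a -0.23). The miR-23 clusters (5 tested) had 0.17 (adjusted p = 0.530), with miR-27a at 0.42 and miR-27b at 0.43. Of 10 tested miRNAs of the imprinted Dlk1-Dio3 clusters, 9 had folds below 0 (median -0.14, adjusted p = 0.138), among them miR-410 at -0.78 and miR-127 at -0.64; its miR-494 had 0.12. This list passed camera without scaling, without day 1 replicate 1 and without day 6 replicate 2, but had adjusted p = 0.898 with an estimated correlation over all arrays, and its median lay above 0 with normexp and with scaling to control probes. The stem cell cluster had 1 tested member, miR-290-5p (-0.14), and the miR-183 cluster had 0.

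Markers of other cell types did not pass either in the model used here. Neuron markers (7 tested) had a median of 0.21 (adjusted p = 0.889), with miR-132 at -0.34 and miR-212 at 0.21. Astrocyte markers (4 tested) had 0.30 (adjusted p = 0.737), with miR-29b at 0.72 and miR-26a at -0.42. Microglia and leukocyte markers (5 tested) had 0.12 (adjusted p = 0.889), with miR-146a at 0.59 and miR-223, a miRNA of myeloid cells, at -0.47. Fibroblast and mural cell markers (3 tested) had 0.80 (adjusted p = 0.285), with miR-143, at the floor on all immature arrays, at 1.05 and miR-199a-3p at 0.80; the latter also stands in the precursor list. The mean of these 3 was 6.02 and 6.79 on day 6 replicates 1 and 2 but 4.69 on replicate 3, against 5.84, 4.84 and 4.71 on day 0 and 4.99 and 4.83 on day 1. This list passed camera in 3 of 30 other settings, among them leaving out day 6 replicate 3 (median 1.44, adjusted p = 0.00162) and no scaling between arrays, and had adjusted p = 0.920 with an estimated correlation over all arrays. MiR-204, the 1 tested marker of epithelium and choroid plexus, had -1.50 ± 0.76 SE (adjusted p = 0.475). Erythroid, endothelium and muscle markers had 0 tested members. Scaling moved miRNAs well above the floor alike, but not those at or near it, since the floor was set after scaling. The median of all miRNAs was -0.28 without scaling and 0.55 with control probes. The signs of list medians nearer to 0 than this can therefore depend on the scaling.

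Between day 6 and day 0, 8 of 199 miRNAs were called, all higher on day 6. MiR-494, the 1 call that the rule named, rose from 8.10 ± 0.13 (SD, n = 3) to 9.27 ± 0.27 (n = 3), a log2 fold of 1.17 ± 0.25 SE (adjusted p = 0.0363). The others were chosen after their values were seen. MiR-714 had the largest fold, 4.37 ± 0.37 SE on the log2 scale (adjusted p = 0.000378). MiR-139-3p rose by 1.86, miR-483 by 1.66, miR-706 by 1.23 and miR-99b by 1.04. Other probes for miR-483 had 1.42, 1.30 and 0.58, and a second for miR-99b 1.19. Another probe for miR-706, detected on 2 arrays, had 0, and its remaining probes were detected on 0 arrays. MiR-711 and miR-710 were not well above background on any day 0 array and were at least 2.94-fold and 1.44-fold higher on day 6. MiR-139-3p lost its call in 16 of 26 other settings, miR-483 in 20, miR-706 and miR-99b in 18 each and miR-711 in 10. MiR-710 lost its call in 15 of 23, miR-494 in 17 of 27 and miR-714 in 0 of 26. At an unadjusted p under 0.05 there were 27. The count was 1 without day 0 replicate 2, without day 0 replicate 3, without day 6 replicate 1 or without day 6 replicate 2. It was 3 without day 6 replicate 3 or either day 1 array, and also 3 with only the arrays of both days in the fit. It was 1 with scaling over all probes, the mean of all probes, the summed signal or only miRNAs detected on all arrays, and 16 with scaling to control probes. The lists were tested in this comparison after the data were seen, and camera called the miR-17 to miR-92a family as lower than other miRNAs (median log2 fold -0.42, adjusted p = 0.0332), but adjusted p = 0.878 with an estimated correlation. The call was also lost without day 0 replicate 2, day 0 replicate 3 or day 6 replicate 2, and with several scalings; the median was 0.092 with control probes, where all miRNAs moved to 0.50.

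Between day 6 and day 1, limma called 0 miRNAs, with 17 at an unadjusted p under 0.05; day 1 had 2 arrays. The 3 with the smallest p did not pass (adjusted p = 0.151). They were miR-690, at 8.51 ± 0.05 on day 6 (SD, n = 3) and 9.64 ± 0.15 (n = 2) on day 1, miR-711, at 6.91 and 4.93, and miR-710, which was not well above background on day 1. Array weights, added after the data were seen, gave 9 calls, and a doubled floor gave 3, all lower on day 6. In the lists, also tested here after the data were seen, camera called the miR-17 to miR-92a family as lower than other miRNAs (median log2 fold -0.59, adjusted p = 0.000115), but adjusted p = 0.770 with an estimated correlation, and the call was lost with scaling over all probes. With scaling to control probes the median was -0.0023, where all miRNAs moved to 0.60. Of its members, 1, miR-92a, was lower adjusted over the list alone.

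Between day 1 and day 0, 3 miRNAs were called, all higher on day 1. MiR-494 rose from 8.10 ± 0.13 (SD, n = 3) to 10.21 ± 0.32 (n = 2), a log2 fold of 2.11 ± 0.28 SE (adjusted p = 0.00396). MiR-714, chosen after its values were seen, rose by 4.60 ± 0.41 SE on the log2 scale (adjusted p = 0.000593), and miR-706, chosen likewise, by 2.22 ± 0.24 SE (adjusted p = 0.00143). Another probe for miR-706, detected on 2 arrays, had a log2 fold of 0.52, and its remaining probes were detected on 0 arrays. MiR-494 lost its call in 4 of 27 other settings, among them scaling over all probes, no scaling and leaving out day 1 replicate 2 (largest adjusted p 0.151), and miR-706 with normexp and with the mean of all probes (largest adjusted p 0.829). MiR-714 kept its call in all 26 other settings. At an unadjusted p under 0.05 there were 16 miRNAs. None of the 14 lists passed camera. The smallest adjusted p, 0.229, belonged to the miR-34 family (4 tested, median -0.84), and the let-7 list, with 8 of 9 members above 0, had a median of 0.24 (adjusted p = 0.277). The miR-17 to miR-92a family had a median of 0.17 (adjusted p = 0.576) and the oligodendrocyte differentiation list -0.02 (adjusted p = 0.868).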

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

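The counts of other splits of the arrays and the fits without single arrays were set beforehand; their use to weigh the background of an array, and all other tests in this part, were chosen after the results were seen. Probes for viral miRNAs entered no comparison above and still gave signal. Bright control probes were used above only for the scaling to control probes. Of the viral miRNAs, 4 were detected on 7 of 8 arrays. Their log2 folds from immature to day 6 cells were -0.020 for mcmv-miR-M23-1-3p, 0.77 for mcmv-miR-M23-1-5p, 0.27 for mcmv-miR-m88-1 and 0.17 for mghv-miR-M1-2. The control probes hur_1, hur_2, hur_4, hur_6 and mr_1 had -0.37, -0.52, -0.72, -0.46 and -0.68 on the same scale. Adjusted over these 9 items, mcmv-miR-M23-1-5p, hur_2, hur_4 and mr_1 shared an adjusted p of 0.0489.

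The higher signal of miR-714, miR-711, miR-710 and miR-139-3p on day 6 was weighed first. Chance could not be excluded: with days 0 and 1 as a single group the real split gave 3 calls, 3 of the 56 splits gave as many, and the highest other gave 4. For day 6 against day 0, the real split of 6 arrays gave 3 calls and the highest other 0, but 10 splits are too few for a share under 0.05; 1 split reached the real count. The background of day 0 replicate 1 was argued against, since 4 of 4 were still called without it. A rise of unspecific signal on all probes stays open, since the upper 95% bound of the viral log2 folds reached 1.37, and with undetected immature arrays set to their lowest detected signal the folds of the 4 were 1.00 (miR-710), 1.13 (miR-139-3p), 1.49 (miR-714) and 1.76 (miR-711). Unspecific signal on single probes and a true change with maturation both stay open, untested.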

How the results depend on the processing

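Array weights, slide row, control-probe scaling and the permutation of list means were chosen after the data were seen; all other settings were planned, and testing the lists in day 6 against day 0 and against day 1 was not. The causes of the changes below were not tested, except that leaving out arrays or using fewer days leaves fewer samples.

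The count of 4 calls in mature against immature cells was 0 with all-probe scaling, normexp, the mean of all probes, the summed signal, no filter, detection on all arrays, the replicate block or slide row, 2 without scaling or with the other detection flag, 11 with array weights and 10 with control-probe scaling. Leaving out arrays gave 0 to 8. The count of 8 for day 6 against day 0 was 1 with all-probe scaling, the mean of all probes, the summed signal, detection on all arrays or the replicate block, 2 without scaling, with normexp or slide row, 3 with only the compared days, 4 with either floor or no filter, 5 with trend and robust moderation and 16 with control-probe scaling. Leaving out arrays gave 1 to 10. The count of 0 for day 6 against day 1 was 3 with a doubled floor or control-probe scaling, 1 with detection on all arrays, 2 with the other detection flag and 9 with array weights, and stayed 0 when any array was left out. The count of 3 for day 1 against day 0 was 1 with detection on all arrays and 2 to 3 when arrays were left out. With 1 array left on day 1, that array is assumed to vary like the others. Settings not listed gave counts near those of the model used here, but not always equal. With days 0 and 1 as a single group, 3 miRNAs were called in mature against immature cells rather than 4.

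Of the lists, the family passed in mature against immature cells, a count of 1. This was 0 with all-probe scaling or an estimated correlation, 3 without scaling, where the fibroblast and Dlk1-Dio3 lists joined, 2 with the replicate block, where the fibroblast list joined, and 1 to 2 without single arrays. For day 1 against day 0 it was 0, but 1 with normexp, a doubled floor, no filter or the other detection flag. For day 6 against day 0 it was 1, but 0 with quantile normalization, no scaling, the summed signal, control-probe scaling or an estimated correlation, 1 with all-probe scaling, where the Dlk1-Dio3 list passed in place of the family, 2 with no filter and 0 to 2 without single arrays. For day 6 against day 1 it was 1, but 0 with all-probe scaling or an estimated correlation, 2 with the replicate block and 1 to 2 without single arrays. Fry and the permutation, which compare a list with no other miRNAs, passed 0 lists. The median log2 fold of the miR-17 to miR-92a family was -0.50 with all-probe scaling and -0.46 with an estimated correlation, and in both the call was lost; the same -0.46 did not pass fry or the permutation. It was 0.088 with control-probe scaling, opposite in sign to -0.46, and 0.092 in place of -0.42 for day 6 against day 0. In both, the family median stayed below the median of all miRNAs, which this scaling also raised. When arrays were left out, the family median in mature against immature cells was -0.59 to -0.35. Without scaling, the median of all miRNAs moved to -0.28 and the family to -0.80. The submitters' values, counted among the other settings, are the same intensities and so could only give identical results.

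Same-numbered arrays of different days did not regularly deviate together (r from -0.71 to 0.32 over 7 pairs, against -0.32 to 0.71 over 14 pairs with different numbers). Deviations were taken from the means of 2 or 3 arrays, so these r values are tied to each other. They cannot decide whether the replicate numbers paired the samples. With the replicate block the counts were 0, 1, 0 and 2 in the order above, and miR-494 lost its call for day 1 against day 0. Of 1642 values of named miRNAs under the alternatives, 177 lost a call and 12 gained 1; no called value changed sign, and 40 changed sign without a call on either side. Of 1593 other values of lists, 16 gained a call, 12 lost 1 and 1 reversed; 152 changed sign without a call on either side. High background limits day 0 replicate 1, where 58 of the 199 tested miRNAs lay at the floor, against 18 to 34 on the others.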

Other observations

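The count of other splits of the arrays, the fits without single arrays, normexp and camera with an estimated correlation were set beforehand; their use to weigh explanations, and all other tests in this part, were chosen after the results were seen. MiR-338-3p, miR-219 and miR-138 rose and fell together from array to array. They were picked from the 7 tested members of the differentiation list, and the other members were not tested in this way. Across the 8 arrays miR-338-3p correlated with miR-138 (Pearson r = 0.975, exact permutation p = 0.000223, adjusted p = 0.00179 over 9 relations; rho = 0.929, p = 0.00223, adjusted p = 0.0201). It also correlated with miR-219 (r = 0.944, exact permutation p = 0.000397, adjusted p = 0.00179; rho = 0.898, p = 0.00516, adjusted p = 0.0232). Without the 2 arrays farthest from the median of miR-338-3p, r was 0.935 and 0.870. With miR-204, a miRNA of choroid plexus, it ran opposite (r = -0.906, exact permutation p = 0.00186, adjusted p = 0.00558; rho = -0.762, p = 0.0368, adjusted p = 0.110), and r was -0.839 without those 2 arrays and -0.911 with day means removed.

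For the spread of miR-338-3p, miR-219 and miR-138 among immature arrays, 2 explanations were argued against as the whole cause. These were the background of day 0 replicate 1 and a wrong label on a single immature array. Whichever immature array was left out, miR-338-3p ranged over at least 3.87 on the log2 scale (3.87 without day 0 replicate 1), against 1.68 on day 6. An exchange of labels between an immature and a day 6 array as part of the cause stays open. Over the 4 miRNAs with the smallest p, chosen anew in each fit, the left-out day 6 replicate 3 lay nearer to day 6 by only 0.30 (root mean square log2 distance). This is less than the SD of 0.74 of this margin over the day 6 arrays. Day 1 replicate 2 lay nearer to day 6 (1.25 against 2.35), which cannot decide, since its 4 miRNAs include miR-714, already high on day 1. The immature arrays with the highest miR-338-3p, day 0 replicate 2 (11.53) and day 1 replicate 1 (11.16), lay nearer to the immature arrays (1.21 against 2.88 and 1.31 against 1.93). Arrays that differed in sensitivity stay open: the 2 with the lowest miR-338-3p, day 0 replicate 1 and day 1 replicate 2, had the fewest mouse miRNAs detected (61 and 150) and the most tested miRNAs at the floor (58 and 34). Against this, day 0 replicate 3, with the next lowest miR-338-3p (8.64), had the most mouse miRNAs detected (218), with 27 at the floor. MiR-338-3p correlated with the number at the floor (r = -0.852, exact permutation p = 0.000595, adjusted p = 0.00119 over 2 relations; rho = -0.850, p = 0.0115, adjusted p = 0.0230; r = -0.841 without those 2 arrays and -0.921 without day 0 replicate 1), but its correlation with the number detected did not pass (r = 0.615, exact permutation p = 0.0758, adjusted p = 0.0758; rho = 0.476, p = 0.243, adjusted p = 0.243; r = -0.537 without those 2 arrays and 0.178 without day 0 replicate 1). Different shares of other cell types cannot be told apart from other causes: 2 of 5 lists of other cell types correlated negatively with miR-338-3p, and only miR-204 passed its test (microglia r = 0.477, exact permutation p = 0.223; astrocytes r = 0.531, p = 0.166; neurons r = 0.225, p = 0.625; fibroblasts r = -0.108, p = 0.816). Cultures that differed in maturity stay open likewise: miR-338-3p correlated with the precursor list at r = -0.530 (exact permutation p = 0.178, adjusted p = 0.320; rho = -0.595, p = 0.132, adjusted p = 0.272; r = -0.356 without those 2 arrays, -0.218 without day 0 replicate 1 and -0.785 with day means removed) and with the miR-17 to miR-92a family at r = 0.316 (p = 0.424, adjusted p = 0.545; rho = 0.286, p = 0.501, adjusted p = 0.644; r = 0.087 without those 2 arrays, -0.010 without day 0 replicate 1 and 0.735 with day means removed).

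The lower miR-17 to miR-92a family on day 6 was weighed last. Chance could not be excluded: 8 of the 56 splits, the real split among them, gave a camera p as small as the real 2.77e-05, and the smallest other was 6.71e-09. All other such splits put day 0 replicate 1 with day 6 arrays, so they do not show that any grouping reaches this p. The family mean on that array was 7.54, against 8.27 to 8.55 on the other immature arrays and 7.54 to 8.03 on day 6. Noise shared by the members within an array may account for the list call, since camera gave p = 0.186 with the estimated correlation. The background of day 0 replicate 1 was argued against, since the median log2 fold was -0.58 without it. In that setting the exact permutation p, not adjusted over the lists, was 0.0286, the smallest that 35 splits can give. Leaving out any other single array gave 0.143 to 0.333. Without day 0 replicate 1, camera with the estimated correlation still did not pass (p = 0.0797, adjusted p = 0.857). A true fall of the family with maturation stays open.

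The imprinted Dlk1-Dio3 list had a lower mean on all 3 day 6 arrays (5.16 ± 0.18, SD) than on all 5 immature ones (5.47 ± 0.11), with an exact permutation p of 0.0179, the smallest that 56 splits can give, and adjusted p = 0.25 over the 14 lists. The median log2 fold of its 10 tested members, -0.14, turned above 0 with normexp (0.04) and with control-probe scaling (0.17, where all miRNAs moved to 0.55). With no detection filter the list took in all 55 members on the array, most of them detected on fewer than 3 arrays. Its median was then 0, which says little about the 10. MiR-494, its 1 member called higher on day 6 against day 0 (log2 fold 1.17) and on day 1 against day 0 (2.11), went the other way.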
